A study of Homo sapiens with 4 samples.

How the data were processed

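The series compares A549 cells, an established human lung carcinoma line, that carry a control vector (shCtl) with A549 cells that carry a hairpin against INSL4 (shINSL4), with 2 arrays per group and 4 in all. Per the series design, pLKO.1 lentiviruses delivered the hairpins and the 2 arrays of a group came from independent cultures. The sources used here do not say whether the cultures of a group go back to 1 transduction, so the p-values measure the spread between these cultures. The titles name 1 hairpin for the knockdown. The control is a scrambled hairpin per the series design and a vector control per the labels, and the sources used here do not settle which. Per the labels' protocols, total RNA was extracted with TRIzol, purified on columns with DNase digestion, and biotin-labelled as single-stranded cDNA for an Affymetrix array.

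The deposited values are on the log2 scale, as their range showed, and were made by the authors with RMA in Affymetrix Expression Console, per the submitters' processing notes. RMA corrects background, brings arrays to a common distribution and summarises probes per transcript cluster. The versions of these tools, the annotation release and its genome build are not given in the sources used here, so no coordinates are printed. Array medians still differed slightly between the deposited columns, and the values were tested without further normalization. The columns hold 67528 transcript clusters. Of these, 23781 had exactly 1 gene symbol in the platform annotation, 1543 had several and 42204 were not listed there and stay unnamed here. Of the single-symbol clusters, 21497 had a gene identifier found in the GRCh38.p14 gene table, which changed 0 symbols and was otherwise used only for older symbols and for neighbours. Where a gene had several clusters (479 genes), the one with the highest mean over the 4 arrays was used, which left 22465 genes; 0 genes had clusters called in opposite directions. No filter on dim genes was applied. An array gives no read depth, and the number of arrays limits the precision: the median standard error of a log2 fold change was 0.0693, with 2 residual and 4.68 prior degrees of freedom.

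Genes were tested in R 4.3.3 with limma 3.58.1 (lmFit with a group term, eBayes, two-sided), and p-values were adjusted over all tested genes with the Benjamini-Hochberg method at a threshold of 0.05. Fold changes are shINSL4 over shCtl, and errors are standard deviations over 2 arrays or limma's standard errors. From textbook knowledge, 37 gene lists with 793 symbols were written, of which 693 symbols matched a tested gene; 36 lists had at least 5 measured members, and the list of mitochondrially encoded genes had 0. Lists were tested with limma's camera at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists, with camera at an estimated correlation and with fry. Camera at an estimated correlation works with the 2 residual degrees of freedom, so it has little power with these arrays. Each list's median was also placed among those of 10000 random lists of the same size drawn from the same 50 bins of mean level, which ignores the correlation between genes. Some lists share members: 6 of the 19 TGF-beta targets and 5 of the 20 BCL2 family genes stand in another list too.

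The genes named in the text followed a rule. It took INSL4 and, in each direction, the 12 genes with the largest change among those past the threshold, with the 4 arrays separated by group and a mean in the higher group above the median level of tested genes. Symbols of small RNAs, olfactory receptors, LOC and LINC genes and open reading frames were left out of that part. The rule added up to 4 members of each list with the smallest p. Genes named outside the rule are said to be chosen after their values were seen. The groups, the tests, the lists, this rule and the alternatives were fixed before the data were examined, except cyclic loess normalization, the gene families and the tests of explanations in the closing part, which came later.

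The alternatives were the replicate number as a block, an intensity trend in the variance with and without robust estimation, leaving out the lowest 40% of genes by level or the genes under the median level in both groups, quantile normalization, centring each array on its median, the mean over a gene's clusters, all clusters tested, an added fold of 1.5, limma's treat against a fold of 1.2, an adjusted p of 0.1, and leaving out each array in turn. Leaving out an array leaves 1 array in its group, so counts of calls from those fits are a description only. The pipeline was tested on simulated data with the 2 arrays per group, the 22465 genes and the spread of these arrays, with 200 genes changed. It recovered 0% of genes changed 1.2-fold, 83.5% of those changed 1.5-fold with 10 false calls, and 98.5% of those changed 2-fold with 8 false calls. Of 200 random lists of 20 unchanged genes, 5 had a camera p under 0.05. The simulated genes varied independently and had no shared shift, unlike the deposited arrays, where 3557 genes passed. These rates therefore need not carry over to the deposited values.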

Results

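Gene expression was measured on 4 Affymetrix arrays of A549 cells, an established epithelial line from a human lung carcinoma. The cells had been transduced with a lentiviral vector, either the control (shCtl) or one for a single short hairpin RNA against INSL4 (shINSL4). The series design calls the control a scrambled hairpin while the sample labels call it a vector control, so it is not certain that the control cells also carried a hairpin. Each group had 2 independently set up cultures, and so 2 arrays, whose number limits the precision of every value. The deposited values were log2 RMA levels of 67528 transcript clusters, and 22465 named genes were tested. The median log2 level of the tested genes was 6.94 and 6.91 on the shCtl arrays and 6.98 and 6.97 on the shINSL4 arrays. Across genes, which are not independent replicates, Pearson's r was 0.997 between the shCtl arrays, 0.998 between the shINSL4 arrays and 0.987 to 0.990 between arrays of different groups.

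The level of INSL4 itself came first, since it checks the group labels. INSL4 encodes a peptide of the insulin and relaxin family that is best known from the placenta. Its log2 level was 8.98 ± 0.0815 (SD, n = 2) in shCtl and 7.24 ± 0.0251 (SD, n = 2) in shINSL4, and both shINSL4 arrays lay below both shCtl arrays. INSL4 fell by 1.73 on the log2 scale (SE 0.0684), a level 3.32-fold lower in shINSL4, at an adjusted p of 0.000142 (limma with Benjamini-Hochberg adjustment). In the GRCh38.p14 gene table the nearest tested neighbours of INSL4 are other genes of its family. None of them passed the threshold in limma with Benjamini-Hochberg adjustment: the log2 fold change was 0.14 (SE 0.0767) for INSL6, -0.01 (SE 0.0875) for RLN2 and 0.08 (SE 0.0786) for RLN1. Of the 17 measured insulin and relaxin family ligands and receptors other than INSL4, 0 were higher and 0 lower, both over all genes tested and when adjusted over the list alone. At an unadjusted p under 0.05, limma gave 0 higher and 1 lower in that list.

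The comparison of shINSL4 with shCtl asked which other genes differ between cells with the hairpin against INSL4 and control cells. Among named genes above the median level, the largest changes were decreases. The 12 decreases given here were each larger than that of INSL4, which was 3.32-fold lower. LAPTM4A, a membrane protein of endosomes and lysosomes, fell by 2.17 on the log2 scale, from 11.45 ± 0.0714 to 9.28 ± 0.0299 (SD, n = 2 each), which is 4.51-fold lower. The proliferation marker MKI67 was 4.01-fold lower, at 10.29 ± 0.0125 in shCtl and 8.28 ± 0.00746 in shINSL4 (SD, n = 2 each), and the DNA topoisomerase gene TOP2A was 3.81-fold lower. PSMD10, an assembly chaperone of the proteasome, was 4.32-fold lower, and SCAMP1, a membrane protein of secretory carriers, was 4.24-fold lower. GDE1, a glycerophosphodiester phosphodiesterase, was 4.02-fold lower, and the succinate receptor gene SUCNR1 was 3.78-fold lower. The purine salvage enzyme gene HPRT1 was 3.74-fold lower and MDH2, the mitochondrial malate dehydrogenase, 3.66-fold lower. SULT2B1, a sulfotransferase that acts on cholesterol and related sterols, was 3.60-fold lower, the prenylcysteine oxidase gene PCYOX1 3.45-fold lower and MLLT11 3.44-fold lower. Adjusted p-values for these 12 genes ran from 0.000142 to 0.000213 (limma with Benjamini-Hochberg adjustment), and for each of them both shINSL4 arrays lay below both shCtl arrays, as the naming rule requires.

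The increases among named genes above the median level were smaller. MAP2, a microtubule-associated protein best known from neurons, rose 2.63-fold, from a log2 level of 6.56 ± 0.0682 to 7.96 ± 0.0376 (SD, n = 2 each). The lipid transporter gene ABCA12 was 2.55-fold higher and SULF2, which removes sulfate groups from extracellular heparan sulfate, 2.38-fold higher. The Polycomb-group gene SCML2 was 2.37-fold higher, and SESN1, a stress-induced gene controlled by p53 and FOXO factors, was 2.27-fold higher. TNRC6A, a scaffold protein of microRNA-mediated silencing, was 1.96-fold higher, ANKRD1, a known target of YAP, 1.90-fold higher, and the kinase gene MAP3K1 1.86-fold higher. ABHD4 was 1.99-fold and LONRF1 1.97-fold higher. FBXW10 at 2.22-fold and FBXW10B at 1.92-fold were also higher, but these are near-identical copies whose signals may not be separable on the array. Adjusted p-values for these 12 genes ran from 0.000154 to 0.00257 (limma with Benjamini-Hochberg adjustment), with both shINSL4 arrays above both shCtl arrays for each, again as the rule requires.

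**Figure D1:**
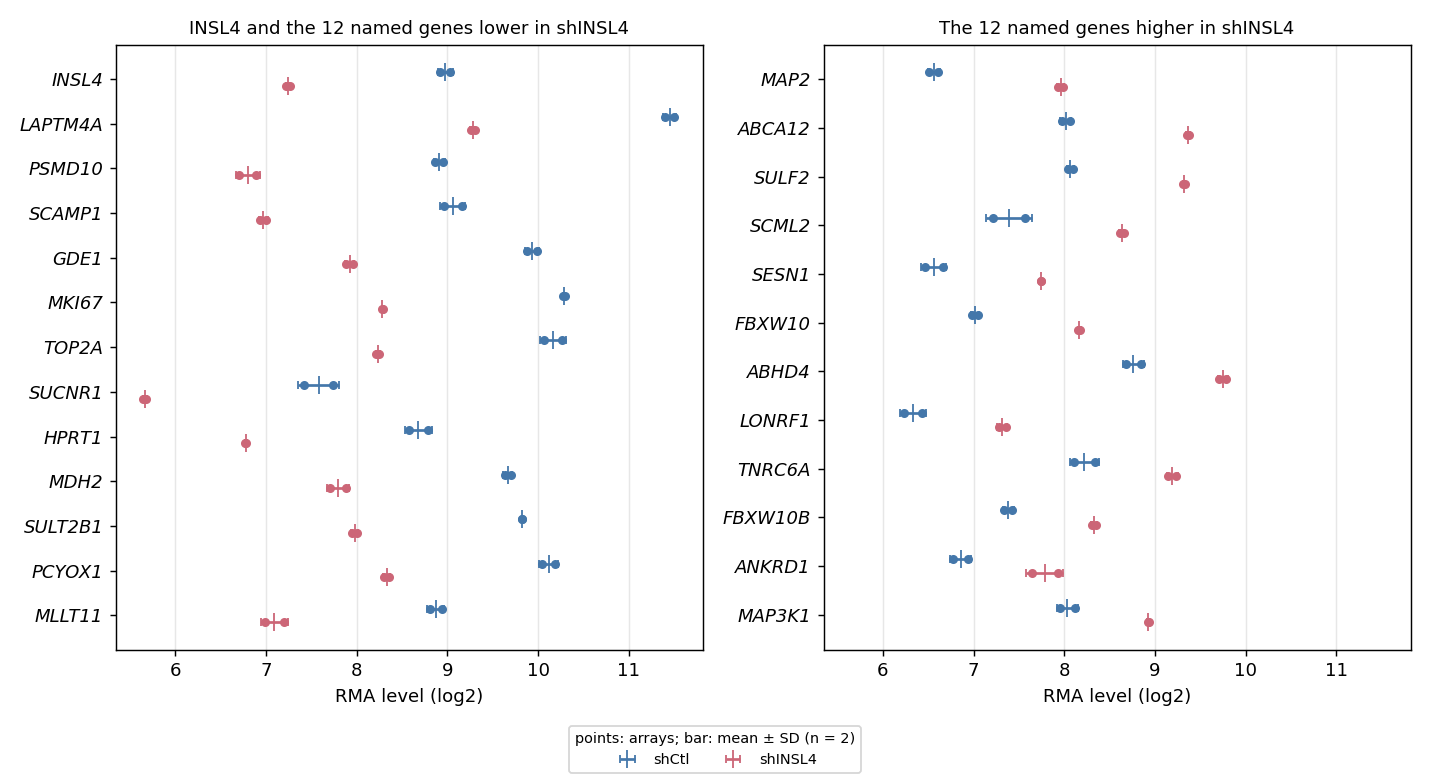
Log2 RMA levels (horizontal axes) of INSL4 and the 12 named genes lower in shINSL4 (left) and of the 12 named genes higher in shINSL4 (right). Points are single arrays and bars the mean ± SD of the 2 arrays of a group; the rule took genes whose groups do not overlap, and INSL4 lay at 8.98 in shCtl and 7.24 in shINSL4.

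In all, 1440 genes were higher and 2117 lower in shINSL4 at an adjusted p under 0.05 (limma with Benjamini-Hochberg adjustment). Most of these changes were small. Changes of at least 1.5-fold were found for 111 of the higher and 671 of the lower genes, and changes of at least 2-fold for 9 higher and 181 lower genes. With single arrays left out, 11 to 14 genes were at least 2-fold higher and 156 to 213 lower. The 4 arrays were separated by group for 68.9% of all tested genes, and for 61.9% after median centring, 59.5% after quantile normalization and 59.0% after cyclic loess. Chance gives 33.3% for 2 arrays against 2 if genes are not shifted together, and genes are not independent. The median log2 fold change of all tested genes was 0.08, and 15466 of them lay above 0. The number of higher genes moved with the scaling: of the genes that passed, 40.5% were higher as deposited, against 25.6% (808 higher, 2347 lower) when each array was centred on its median, 27.5% (904 higher, 2381 lower) after cyclic loess normalization and 35.2% (1266 higher, 2334 lower) after quantile normalization. Higher calls outnumbered lower ones with the replicate number as a block, at 53.5% (2996 higher, 2605 lower), without shCtl replicate 1, at 55.2% (2999 higher, 2430 lower), and at an adjusted p under 0.1, at 52.7% (2955 higher, 2647 lower), so the balance of all calls depends on the fit. Without shINSL4 replicate 1 there were 892 higher and 1403 lower genes, and without shINSL4 replicate 2 there were 808 and 1618.

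**Figure D2:**
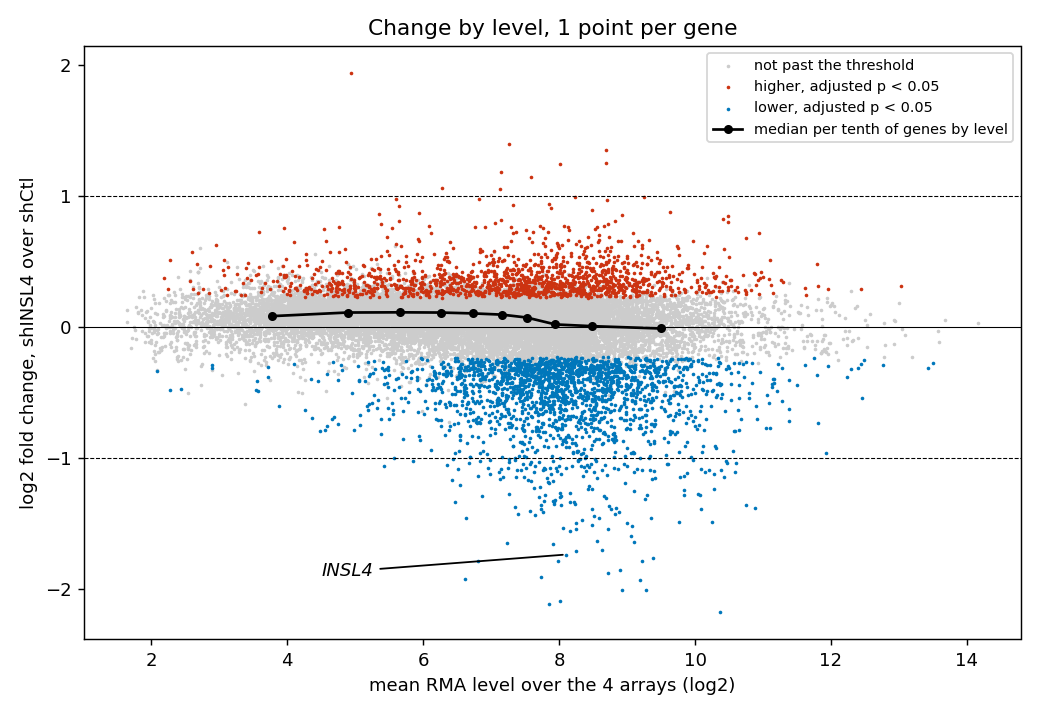
Log2 fold change of shINSL4 over shCtl (vertical axis) against the mean log2 RMA level over the 4 arrays (horizontal axis), 1 point per gene, with genes past the threshold in colour and dashed lines at a 2-fold change. The black line joins the medians of 10 equal bins of genes by level, which run from 0.11 in dimmer bins to -0.01 in the brightest; below the lower dashed line lie 181 genes that passed and above the upper one 9.

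Genes of cell division were lower as a group. Of 29 measured genes of the G2 and M phases, 27 fell and 0 rose (28 and 0 when adjusted over the list alone), with a median log2 fold change of -0.58. Besides MKI67 and TOP2A these included the spindle gene NUSAP1, which was 2.47-fold lower, and the centrosomal kinase gene NEK2, which fell by 0.95 on the log2 scale. Of 29 measured genes of the G1-S transition and DNA replication, 16 fell and 0 rose (20 and 2 when adjusted over the list alone), with a median of -0.31. The cyclin E gene CCNE1 fell by 1.23, the thymidine kinase gene TK1 by 0.85, the GINS-complex gene GINS1 by 0.83 and the checkpoint gene CLSPN by 0.72 on the log2 scale. The adjusted p was 2.17e-27 for the G2 and M list and 6e-11 for the G1-S list (camera with Benjamini-Hochberg adjustment). With an estimated correlation both lists had an adjusted p of 0.508; over the 13 refits at the preset correlation it ran from 1.19e-47 to 1.68e-17 and from 5.58e-11 to 1.18e-05. Of 9 measured replication-dependent histone genes, 1 was higher and 2 lower, and that list did not pass (adjusted p = 0.366, camera with Benjamini-Hochberg adjustment).

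Targets of the transcription factor p53, which A549 cells carry in wild-type form, were higher as a group. Of 24 measured targets, 13 rose and 3 fell (14 and 3 when adjusted over the list alone), with a median log2 fold change of 0.38. The survival gene TRIAP1 rose by 0.81 on the log2 scale, the RNA-binding protein gene ZMAT3 by 0.74, the mitochondrial quality-control gene SPATA18 by 0.73 and the DNA repair gene XPC by 0.71. MDM2, the ubiquitin ligase that limits p53, rose by 0.83 and the cell cycle inhibitor gene CDKN1A by 0.51; these members, and the 3 that fell, were chosen after their values were seen. The 3 were RRM2B at -0.63, CYFIP2 at -0.59 and ACTA2 at -0.34. The list does not hold every p53 target. Outside it, SESN1 rose by 1.18 and CCNG1, which p53 also controls, fell by 1.06 on the log2 scale. Both were picked here after their values were seen. The adjusted p of the list was 0.000798 (camera with Benjamini-Hochberg adjustment), and with an estimated correlation the adjusted p was 0.508; over the 13 refits at the preset correlation it ran from 3.58e-06 to 0.0122. In the list of BCL2 family and death receptor genes, 3 of 20 were higher and 2 lower. The death receptor gene TNFRSF10A rose by 0.50 and the p53-induced gene PMAIP1 by 0.47 on the log2 scale, while BID fell by 0.61. That list did not pass (adjusted p = 0.905, camera with Benjamini-Hochberg adjustment).

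Several groups of signalling targets held more lower than higher genes. Of 19 measured TGF-beta targets, 6 fell and 0 rose (7 and 1 when adjusted over the list alone), with a median of -0.21; the matrix gene TGFBI fell by 1.12, IGFBP3 by 0.75 and SKIL by 0.69 on the log2 scale. Among 22 NF-kB targets and inflammatory cytokines, 7 fell and 1 rose (9 and 1 when adjusted over the list alone), with a median of -0.06. The neutrophil-attracting chemokine genes CXCL5, CXCL8 and CXCL1 fell by 1.16, 0.87 and 0.86. Among 24 targets of CREB and its CRTC coactivators, which are active in LKB1-deficient cells such as A549, 6 fell and 1 rose (8 and 2 when adjusted over the list alone), with a median of -0.11. The hormone gene STC1 fell by 1.39, the long noncoding RNA LINC00473 by 0.96 and PPARGC1A by 0.48 on the log2 scale. Adjusted p-values were 0.00209 for the TGF-beta and the NF-kB lists and 0.00305 for the CREB list (camera with Benjamini-Hochberg adjustment), and with an estimated correlation the adjusted p was 0.583, 0.637 and 0.583. The NF-kB list had an adjusted p of 0.0512 without shCtl replicate 1 (range over the 13 refits 4.36e-05 to 0.0512), and the CREB list one of 0.0613 with the dimmest 40% of genes left out (range 0.00191 to 0.0613).

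Among 21 genes that report ERK pathway output, 5 fell and 1 rose (5 and 2 when adjusted over the list alone), with a median of -0.06. The ETS-factor gene ETV4 fell by 0.70, the cytokine gene LIF by 0.73 and IER3 by 0.60 on the log2 scale. The adjusted p was 0.0180 (camera with Benjamini-Hochberg adjustment) and 0.583 with an estimated correlation. The call was lost with quantile (0.147) or cyclic loess (0.0869) normalization, with either level filter, and without shCtl replicate 1 (0.0678), shINSL4 replicate 1 (0.0773) or shINSL4 replicate 2 (0.0763), with a range of 0.0154 to 0.174 over the 13 refits. Among 22 targets of YAP and TEAD, 4 were higher and 2 lower (5 and 2 when adjusted over the list alone): besides ANKRD1, NT5E rose by 0.77, while AXL fell by 0.62 on the log2 scale. Among 21 FOXO targets, which rise when PI3K-AKT signalling is low, 5 were higher and 4 lower (5 and 5 when adjusted over the list alone, 3 and 5 after centring or cyclic loess). Against the rise of SESN1, the kinase gene PDK4 fell by 1.08, CCNG1 by 1.06 and ERBB3 by 0.72 on the log2 scale. Neither the YAP list (adjusted p = 0.814) nor the FOXO list (adjusted p = 0.905) passed camera with Benjamini-Hochberg adjustment, nor did the insulin and relaxin family list (adjusted p = 0.905). The FOXO list's median was 0.09 while its test pointed down, and the YAP list's median was 0.04, or -0.01 after centring, with a test that also pointed down.

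Of 19 glycolysis genes, 7 fell and 0 rose (8 and 1 when adjusted over the list alone), with a median of -0.15; PGAM1 fell by 0.82, ENO2 by 0.61 and LDHA by 0.40 on the log2 scale. Of 19 genes of the unfolded protein response, 7 fell and 0 rose (9 and 0 when adjusted over the list alone), with a median of -0.05. HERPUD1, a component of endoplasmic reticulum degradation, fell by 0.67, DNAJC3 by 0.47 and SEL1L by 0.42. The adjusted p was 0.000798 for glycolysis and 0.000771 for the unfolded protein response (camera with Benjamini-Hochberg adjustment), and with an estimated correlation the adjusted p was 0.508 and 0.602. Among 10000 random lists of the same size and level, the median of the glycolysis list lay at percentile 1.47 and that of the unfolded protein response at 17.7. The latter median is not unusual for genes of its level. The percentile covers the median only, and the mean of the unfolded protein response list was lower, at -0.17. Of 21 autophagy and lysosome genes, 6 fell and 2 rose (7 and 3 when adjusted over the list alone), with a median of -0.06, and the autophagy initiation gene BECN1 fell by 1.52 on the log2 scale. That list had an adjusted p of 0.0145 (camera with Benjamini-Hochberg adjustment) and of 0.602 with an estimated correlation. Its call was lost with quantile (0.235) or cyclic loess (0.0947) normalization and with either level filter, with a range of 0.0121 to 0.235 over the 13 refits.

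Of 16 heat-shock response genes, 3 fell and 0 rose (4 and 0 when adjusted over the list alone), with a median of -0.11, and the cochaperone gene DNAJB1 fell by 0.56 on the log2 scale. Of 22 nuclear genes of oxidative phosphorylation, 3 fell and 0 rose, over all genes and when adjusted over the list alone, with a median of -0.04; the complex I gene NDUFA9 fell by 0.81 and the complex III gene UQCRC1 by 0.41. Adjusted p-values were 0.00869 and 0.0145 (camera with Benjamini-Hochberg adjustment), and both lists had an adjusted p of 0.711 with an estimated correlation. Their medians lay at percentiles 5.61 and 18.3 of the random lists of the same level. Both calls were lost with quantile (0.140 and 0.227) or cyclic loess (0.0678 and 0.102) normalization and with either level filter. They were also lost without shINSL4 replicate 1 (0.119 and 0.209), shCtl replicate 2 (0.1002 and 0.150) or shINSL4 replicate 2 (0.0674 and 0.05005). Over the 13 refits of camera the adjusted p ran from 0.00227 to 0.140 for the heat-shock list and from 0.00275 to 0.227 for oxidative phosphorylation. Of 13 fatty acid synthesis genes, 4 fell and 1 rose, among them ACLY, which fell by 0.72, and FASN, which fell by 0.59. Of 20 genes of cholesterol synthesis and uptake, 4 rose and 2 fell, with INSIG1 up by 0.50 and MSMO1 up by 0.55 on the log2 scale. In the list of ATF4 targets, 1 of 23 rose and 4 fell, including WARS1, which fell by 0.79, and the amino acid transporter gene SLC7A5, which fell by 0.60. Of 19 hypoxia-induced genes, 2 rose and 3 fell: the glucose transporter gene SLC2A3 rose by 0.72 and NDRG1 fell by 0.60. These 4 lists did not pass (adjusted p = 0.0886, 0.598, 0.0988 and 0.0774, camera with Benjamini-Hochberg adjustment).

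**Figure D3:**
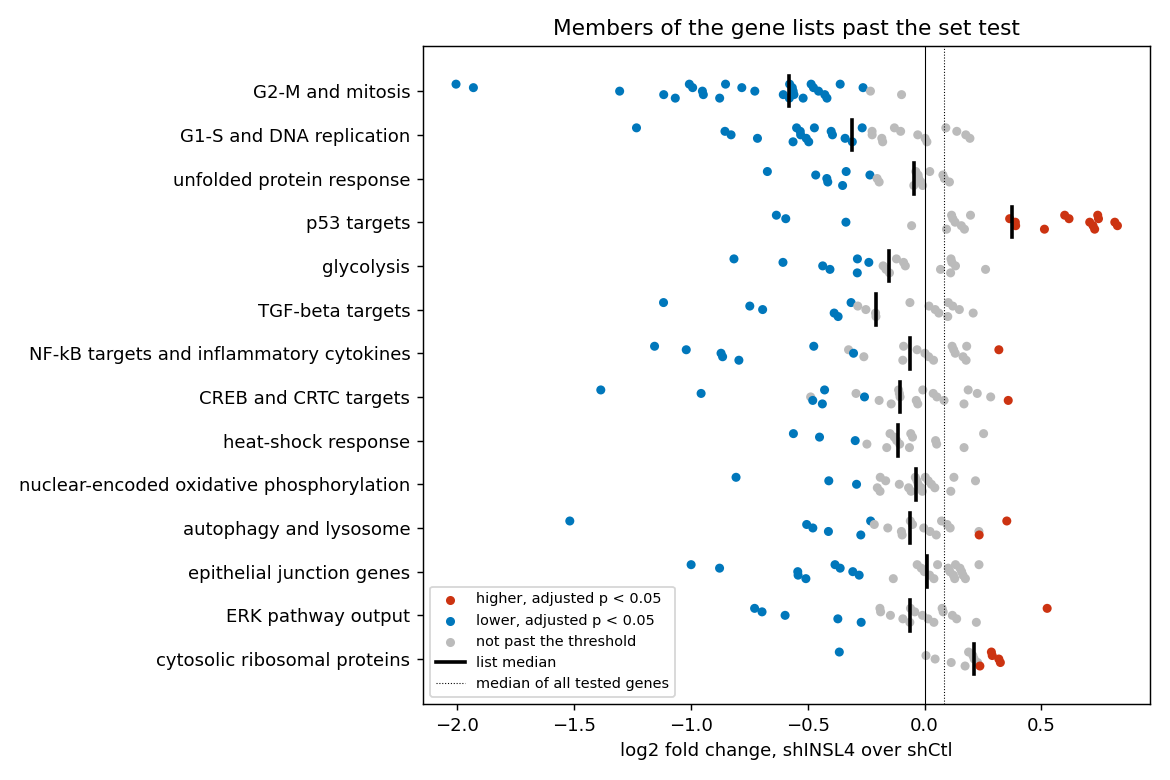
Log2 fold change of shINSL4 over shCtl (horizontal axis) of the members of the 14 gene lists that passed the set test, 1 point per gene, with the median of each list as a bar and the median of all tested genes (0.08) as a dotted line. The bar lies at -0.58 for the G2 and M list and at 0.38 for the p53 targets, and between -0.31 and 0.21 for the other lists.

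Of 26 epithelial junction and keratin genes, 9 fell and 0 rose (9 and 1 when adjusted over the list alone). The tight-junction gene OCLN fell by 1.00, the desmosomal gene DSG2 by 0.88, KRT18 by 0.54 and the E-cadherin gene CDH1 by 0.51 on the log2 scale. The list's median was 0.01 while its mean was -0.13 and its test pointed down, at an adjusted p of 0.0179 (camera with Benjamini-Hochberg adjustment) and of 0.626 with an estimated correlation. The median was -0.02 after quantile normalization, -0.04 after centring and -0.04 after cyclic loess. The call was lost with quantile (0.0628) or cyclic loess (0.0578) normalization, with either level filter and without shCtl replicate 1 (0.111), with a range of 0.00554 to 0.111 over the 13 refits. Of 23 mesenchymal and matrix genes, 1 was higher and 1, the matrix enzyme gene LOXL2, fell by 0.71 on the log2 scale. In that list 0 were higher and 2 lower after centring, 1 and 3 after quantile normalization, and 1 and 2 after cyclic loess. Of 21 alveolar and airway secretory genes, 0 were higher and 3 lower, at 3 and 4 with an unadjusted p under 0.05 in limma. Neither list passed (adjusted p = 0.905 and 0.913, camera with Benjamini-Hochberg adjustment).

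Of 14 measured cytosolic ribosomal protein genes, 5 rose and 1 fell (10 and 1 when adjusted over the list alone), with a median of 0.21. After median centring 2 were higher and 1 lower, after quantile normalization 7 and 1, and after cyclic loess 4 and 1. RPS3 rose by 0.32 and RPL8 fell by 0.36 on the log2 scale; without shINSL4 replicate 1 neither passed the threshold (0.33 and -0.33), and RPS3 did not without shINSL4 replicate 2 either (0.30). The list's adjusted p was 0.0377 (camera with Benjamini-Hochberg adjustment) and 0.641 with an estimated correlation. The call was lost without shCtl replicate 1 (0.195), shINSL4 replicate 1 (0.123) or shINSL4 replicate 2 (0.185) and with the replicate number as a block (0.0539), with a range of 0.000785 to 0.195 over the 13 refits. Of 21 genes of ribosome biogenesis, 1 was higher and 4 were lower, including NOP58, which fell by 1.25, and the list did not pass (adjusted p = 0.181, camera with Benjamini-Hochberg adjustment).

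A549 cells have an active NRF2 programme, since their KEAP1 gene is mutated. Of 23 NRF2 targets, 8 rose and 3 fell (8 and 5 when adjusted over the list alone): CYP4F11 rose by 0.68 and the glutathione synthesis gene GCLM by 0.55, while TRIM16L fell by 0.69 on the log2 scale. The median was -0.06, the mean 0.04, and the list did not pass (adjusted p = 0.680, camera with Benjamini-Hochberg adjustment). Of 23 placental trophoblast genes, 5 rose and 4 fell (6 and 4 when adjusted over the list alone, 3 and 5 after quantile or cyclic loess normalization). The 5 were all pregnancy-specific glycoprotein genes, led by PSG4 at 0.75 and PSG1 at 0.43, which are near-identical copies and so uncertain as separate genes; EPAS1 fell by 0.52 and PAPPA by 0.45. Of 19 acute-phase and complement genes, 5 fell, among them the fibrinogen gene FGG by 1.00 and CP by 0.62, and 0 rose. Of 8 metallothionein genes, 2 rose and 0 fell (1 and 0 after centring or cyclic loess), with MT2A up by 0.62 on the log2 scale. These lists did not pass either (adjusted p = 0.814, 0.0886 and 0.0802, camera with Benjamini-Hochberg adjustment).

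Genes that can respond to a hairpin vector were measured in 3 lists; the sources differ on whether the control carried a hairpin, so hairpin load may differ between the groups. Of 31 interferon-stimulated genes, 1 rose and 4 fell, with OAS3 down by 0.70 and OAS1 down by 0.67 on the log2 scale. Of 11 genes of PKR and cytosolic RNA sensing, 2 were higher and 1 lower (1 and 1 after centring): the RNA-editing enzyme gene ADAR fell by 0.74 and TLR3 rose by 0.72. Of 8 measured genes of small RNA processing, 2 rose and 2 fell. DROSHA fell by 1.04, while DICER1 rose by 0.61 and TNRC6A by 0.97. The listed genes AGO1, AGO2, AGO3, AGO4 and DGCR8 matched no tested gene, so the list does not cover them. None of the 3 lists passed as deposited (adjusted p = 0.167, 0.905 and 0.905, camera with Benjamini-Hochberg adjustment), and the interferon list had an adjusted p of 0.0494 after quantile normalization (range over the 13 refits 0.0494 to 0.620). The median of the interferon list, -0.01, nevertheless lay at percentile 0.04 of the random lists of the same level, so a lower level of these genes is not ruled out. Markers of other cell types gave no list past the threshold. Of 12 endothelial markers 0 passed in limma, with 4 higher and 0 lower at an unadjusted p under 0.05. Of 11 fibroblast markers 1 was higher and 1, LUM, fell by 0.78 (0 higher and 1 lower after quantile or cyclic loess normalization). LUM lay at 4.95 in shCtl and 4.17 in shINSL4, around the median level of the olfactory receptors (4.41). It is not shown to be above background. Of 13 leukocyte markers only CD68, a lysosomal protein gene, fell, by 0.81 on the log2 scale. Adjusted p-values of these lists were 0.135, 0.650 and 0.701 (camera with Benjamini-Hochberg adjustment).

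Of the 36 lists tested, 14 passed camera at an adjusted p under 0.05, 2 of them shifted up and 12 down. With an estimated correlation within the lists 0 passed, the smallest adjusted p being 0.508, and 2 lists, those of the G2 and M phases and of G1-S, had an unadjusted p under 0.05. That form of camera works with 2 residual degrees of freedom, so few lists could pass. It cannot tell correlation between genes from low power. The estimated correlation was -0.027 for G1-S, 0.003 for p53 and 0.005 for glycolysis, below the preset 0.01. It was higher for others, such as 0.18 for the G2 and M list and 0.47 for heat-shock. Camera does not match genes on level, and brighter genes had lower medians. Among the 10000 random lists matched on level, taken as a description only, the medians of the other lists that passed lay at percentile 0 for the G2 and M and the G1-S lists, 0.05 for TGF-beta, 0.30 for CREB, 1.56 for NF-kB, 3.87 for ERK, 9.89 for autophagy, 13.3 for the epithelial list, 99.9 for the cytosolic ribosomal proteins and 100 for p53. By limma's fry test, which asks whether the genes of a list move one way on balance without comparing them with other genes, 5 lists passed, namely the G2 and M, G1-S, p53, glycolysis and metallothionein lists. In the lists described with 0 higher genes, limma gave at an unadjusted p under 0.05 higher genes numbering 0 for the G2 and M, unfolded protein response and acute-phase lists, 1 for the glycolysis, TGF-beta and oxidative phosphorylation lists, and 2 for the G1-S, heat-shock and epithelial lists.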

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

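The tests of explanations in this part were all chosen after the results were seen. Transcript clusters without a gene name here were outside the comparisons of genes, and 11 of them were at least 2-fold higher in shINSL4 than in shCtl at an adjusted p under 0.05 (limma with Benjamini-Hochberg adjustment over all clusters). They make 10 distinct profiles, since 2 of them have identical values. Among named genes, 9 rose as much. The largest of these clusters was 4.97-fold higher, a log2 fold change of 2.31 (SE 0.117), with both shINSL4 arrays above both shCtl arrays. It stays unnamed here. Of the 42204 unnamed clusters, 271 were higher and 517 lower, and 142 were at least 2-fold lower.

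Changes of at least 2-fold were mostly decreases, with 181 genes lower and 9 higher, or 156 to 213 and 11 to 14 with single arrays left out. A difference in intensity distribution between the arrays was tested with cyclic loess normalization, which removes any trend of the difference with level. It left 198 genes at least 2-fold lower and 7 higher. The medians of the level bins lay between -0.01 and 0.11, which is small against a 2-fold change. Removing so small a trend could not have evened out these counts, so the result was fixed before the test. Differences between the arrays that do not follow level were not tested. Off-target activity of the single hairpin may add to the decreases and stays open: the design holds 1 hairpin against INSL4, so its effect and that of lower INSL4 cannot be told apart. The 12 named decreases, taken as the largest, ran from 3.44-fold to 4.51-fold, against 3.32-fold for INSL4. This order does not decide the question. A loss of INSL4 is the biological explanation that the design names, and it stays among the open ones.

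The median change of the dimmer genes lay above 0. In 10 equal bins by level it was 0.09 to 0.11 in the 4 dimmest and -0.01 in the brightest, while genes called higher were most numerous in the 2 brightest (235 and 246, against 87 to 117 in the 4 dimmest). Of 644 genes in families that lung epithelial cells do not use (olfactory receptors, keratin-associated proteins, T-cell receptor and immunoglobulin segments), 81.8% lay above 0, with a median log2 fold change of 0.13, against 68.8% of all tested genes and 79.0% of the other genes below the median level. A raised floor on the shINSL4 arrays may give such values and stays open, because these families were picked after a scan for shifted groups. In these families 46 genes were called higher and 1 lower as deposited, and 14 higher and 7 lower after cyclic loess, which draws the difference at each level towards 0 whatever its cause and so does not decide between causes. No biological explanation was tested for this pattern.

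Mitotic genes were lower while p53 targets were higher. Scaling that depends on level was examined with cyclic loess normalization. After it the median log2 fold change was -0.58 for the mitosis list and 0.36 for the p53 targets, against -0.58 and 0.38 as deposited. The trend it removes was small, with medians of the level bins between -0.01 and 0.11. It could not have brought these medians near 0, so the result was fixed before the test. A level trend of that size is too small to give these medians. A different growth state of the cultures unrelated to the hairpin, such as density at harvest, may give the same values: for 29 of 29 members of the mitosis list both shINSL4 arrays lay below both shCtl arrays, which cultures that differ in growth for either reason would show. With 2 cultures per group these explanations cannot be told apart, and a slower cell cycle after loss of INSL4 remains a hypothesis.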

How the results depend on the processing

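Cyclic loess normalization was the only alternative here chosen after the data were seen. INSL4 stayed lower and past the threshold in every fit, between -1.79 and -1.68 on the log2 scale with single arrays left out. No gene that passed as deposited changed sign in any fit. The number of higher genes was 1440 as deposited. It was 2223 without the lowest 40% of genes and 2173 without genes under the median level in both groups. Those fits test fewer genes and also estimate the shared spread anew from them, and which of these mattered was not tested. The number of higher genes was 808 with median centring, 904 with cyclic loess and 1266 with quantile normalization. It was 499 of all clusters tested. It was 111 with an added fold of 1.5, 109 with treat and 2955 at an adjusted p under 0.1. Single arrays left out gave 808 to 2999. The 2117 lower genes became 671 with an added fold of 1.5, 677 with treat and 1403 to 2430 with single arrays left out. Of the lists, 14 passed as deposited, 8 without the lowest 40% of genes, 9 without genes under the median level in both groups, 9 with cyclic loess, 0 with an estimated correlation, 5 with fry, and 10 to 12 with single arrays left out. Where no reason is given, the cause was not tested. With 1 array left out, the lone array of its group is assumed to vary like the other group, with 1 residual degree of freedom. In the fits without a shINSL4 array, limma's prior outweighed that degree of freedom. Genes there were in effect judged by fold change against 1 common spread. Counts of genes and lists from fits with 1 array left out are therefore a description only.

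With the replicate number as a block, 2996 genes were higher and 2605 lower, all 3557 calls were kept, and 13 lists passed, without the cytosolic ribosomal proteins. In the titles, both replicate 1 arrays carry codes that begin with WA and both replicate 2 arrays codes that begin with WB. No label says that a number or code marks a shared day or batch, so pairing of the cultures is possible but not known. Same-numbered arrays had deviations from their group means that correlated at 0.232 across genes.

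The next counts cover the other genes taken by the naming rule, whether or not the text names them, and no genes outside it. Over the alternatives these genes kept their side of the threshold in 2397 fits, lost the call in 234 and gained it in 73. In 0 fits the change reversed. The lists kept their side of the threshold in 427 fits, lost the call in 36 and gained it in 1. The lists of the G2 and M phases, G1-S, p53, glycolysis, the unfolded protein response and TGF-beta targets kept their call in every refit of camera at the preset correlation. Signal near background limits the dim genes, whose small rises depend on the scaling.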

Other observations

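The groups in this part were chosen after the data were seen. They came from a scan of 217 stems of gene symbols with at least 12 genes each, of which 26 passed camera, so the adjusted p-values of the 20 families then defined understate the search. The SNORD116 small nucleolar RNAs, a cluster of near-identical copies from the imprinted Prader-Willi region, were lower: of 19 measured copies, 18 fell and 0 rose, with a median log2 fold change of -0.79. SNORD116-17 fell by 1.05 and SNORD116-26 by 0.82 on the log2 scale. The copies may share signal on the array and are not independent genes; the median was -0.79 after quantile and after cyclic loess normalization too, and 16 copies were still lower after cyclic loess. The neighbouring SNORD115 copies, at a median level of 2.36, gave 1 higher and 0 lower of 31. Among 64 box H/ACA small nucleolar RNAs, which guide pseudouridylation, 12 rose and 0 fell, with a median of 0.19; 12 were higher and 2 lower after cyclic loess, 15 and 1 after quantile normalization, and 6 and 1 after median centring, with medians of 0.14 to 0.16. Adjusted p-values were 4.45e-15 for SNORD116 and 0.000493 for the H/ACA RNAs (camera with Benjamini-Hochberg adjustment), and 0.554 for both with an estimated correlation.

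Of 52 proteasome subunit and assembly genes, 14 fell and 1 rose, and besides PSMD10, PSMD2, a subunit of the regulatory particle, fell by 1.63 on the log2 scale. Of 28 genes of the adaptor protein complexes, which sort cargo into vesicles, 10 fell and 0 rose, led by AP3D1, which fell by 1.43. Of 42 kinesin genes, 13 fell and 0 rose; KIF11, which separates the spindle poles, fell by 1.07 and KIF20A by 0.85. Of these 13, 4 stand in the G2 and M list and so repeat it. Of the other 38 kinesins, 9 fell and 0 rose, with a median of 0.00. Their adjusted p was 0.00465 (camera at the preset correlation with Benjamini-Hochberg adjustment), and an estimated correlation was not used for them. The G2 and M list does not hold every mitotic gene, so the other kinesins may repeat it too. Of 57 translation initiation factor genes, 11 fell and 2 rose, with EIF3M down by 0.92. Counts after cyclic loess were 14 lower and 1 higher for the proteasome, 10 and 0 for the adaptors, 13 and 0 for the kinesins and 9 and 2 for the initiation factors. The medians were -0.01, -0.10, -0.03 and -0.01, against 0.08 for all tested genes. They lay at percentiles 10.4, 0.23, 0.35 and 7.52 of 10000 random lists of the same size and level. Adjusted p-values were 0.000609, 0.000129, 0.000129 and 0.00238 (camera with Benjamini-Hochberg adjustment), and 0.566, 0.554, 0.554 and 0.566 with an estimated correlation.

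IFNE, an epithelial type I interferon gene, was higher at a low level, which is why the rule for named genes left it out. Its log2 level was 3.97 ± 0.216 in shCtl and 5.91 ± 0.0991 in shINSL4 (SD, n = 2 each). The shCtl level lay below the median level of the olfactory receptors (4.41), which these cells do not use, so it is not shown to be above background and the size of the rise stays uncertain. IFNE overlaps the long noncoding RNA gene MIR31HG in the GRCh38.p14 gene table, and MIR31HG was higher too, by 0.99 on the log2 scale (SE 0.0775), so their signals are uncertain as separate genes. The other interferon genes measured nearby did not pass in limma with Benjamini-Hochberg adjustment: IFNA1 was at 0.26 (SE 0.116), IFNA8 at 0.09 (SE 0.192) and IFNA2 at 0.10 (SE 0.0706).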
